A study of Homo sapiens with 3 samples.

How the data were processed

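RNA was measured on 3 microarrays, 1 per group. The groups were human foreskin fibroblasts (HFF) given 5 cardiac regulators (MYOCD, which encodes myocardin, TBX5, MEF2C, HAND2 and GATA4) by transduction, here called HFF_5F, adult human heart tissue as the positive control, and untransduced HFF as the negative control. Per the labels, RNA of the transduced cells was collected 4 weeks after transduction, and Cy3-labelled RNA was hybridised. The deposited values are log2 expression values per transcript cluster, a set of probes that targets 1 transcribed region. They were made with RMA, per the submitters' processing notes; the software, its version and its parameters are not given in the sources used here. RMA corrects background, brings the probe values of all arrays to 1 distribution and summarises each cluster by median polish. With 3 arrays, median polish often returns exactly equal values for clusters that differ little, and it understates differences that are small or limited to part of the probes. In simulated clusters of unchanged genes, 76.3% with 24 probes and 82.6% with 25 probes were equal between a pair of arrays. A true log2 difference of 0.5 in all probes was returned as 0.36, and a difference of 3 as 2.88. A difference of 3 in 60% of the probes was returned as 2.48 and in 40% as 0.22, so a value near that of HFF does not exclude a change seen by 40% of the probes.

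The table held 33297 transcript clusters and no column outside the 3 arrays. In the platform annotation 19460 clusters had 1 gene, 1754 had several and 12083 had none listed. Of the single-gene clusters, 19429 matched a gene identifier of the RefSeq gene table, and 0 symbols needed an update. After leaving out Y-linked genes and the X-inactivation transcripts, 19436 clusters of 18394 genes were used. For the 768 genes with several clusters, the cluster with the highest mean over the arrays was taken. A gene entered the counts if its highest value was at or above 6.85, the 50th percentile of all values, which left 12891 genes. No coordinates are given, because no genome build was tied to the values.

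The array medians were 6.82 for HFF_5F, 6.87 for heart and 6.85 for HFF. The number of arrays limits the precision. With 1 array per group there was no test, no p-value and no spread between replicates, so every difference below describes these 3 arrays and has no replicate check. Detection calls were not used here, so a low value cannot be read as absence. For each of the 3 pairs of arrays the difference of log2 values was taken per gene, where a difference of 1 is 2-fold, and genes past 2-fold were counted in each direction. Heart-enriched genes were at least 4-fold higher in heart than in HFF, and fibroblast-enriched genes at least 4-fold lower. The share of these that moved at least 2-fold the same way in HFF_5F has an exact binomial 95% interval, which covers counting error over genes only. Both differences use the HFF array, so the shares were also simulated for unchanged transduced cells in 100 draws.

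The 33 gene lists, the comparisons, the thresholds and the rule for named genes were fixed before the data were examined. The lists had 670 entries, of which 608 were measured; the others were not analysed here. The median of each list was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays. Many random lists of dim genes have a median of exactly 0, so a small list median can pass most of them. Named genes were the 5 transduced factors, the 15 largest and 15 smallest differences of HFF_5F against HFF, the 10 largest and 10 smallest of the other comparisons, and the 8 genes furthest above and 8 furthest below both controls. Up to 4 members of each list with the largest absolute difference were added, and up to 6 members past 2-fold and 6 within 2-fold for the sarcomere, calcium, ion channel and transcription factor lists. Of the named genes, 8 had several clusters, and 1 of these, AKR1C1, had clusters that differed by more than 1. Of all genes past 2-fold for HFF_5F against HFF, 53 had several clusters. All clusters had the same direction for 46 of these and all passed 2-fold for 32.

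Alternatives were other scalings (array medians, quantile normalization again, cyclic loess, housekeeping genes), the mean of a gene's clusters, other filters and other thresholds. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and in R 4.3.3 with limma 3.58.1 for the scalings. The steps were tested on simulated data made from the 12891 genes. For HFF_5F against HFF, 94 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 3 were recovered, and 9 of 12691 unchanged genes passed 2-fold. The noise in these simulated data was a chosen value, not estimated from these arrays. These counts therefore check the steps and are not error rates of the arrays.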

Results

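Gene expression was compared among 3 arrays: fibroblasts transduced with 5 cardiac transcription factors (HFF_5F), adult heart tissue, and untransduced foreskin fibroblasts (HFF). HFF are primary skin cells grown in culture. The series asks how far the factors move fibroblasts toward a cardiac fate, and the transduced cells were sampled after 4 weeks. Each group had 1 array, so there are no replicates, and no difference below can be set against replicate error. The arrays included 0 of vector-only or time-matched cells. In every comparison of HFF_5F with HFF, culture time, vector or selection therefore cannot be told apart from the factors.

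Of the transduced factors, 4 were higher in HFF_5F than in HFF. MEF2C was higher by 3.53 on the log2 scale, MYOCD by 3.02, GATA4 by 1.65 and TBX5 by 1.62. HAND2 was equal at 8.50 in both, and stood at 8.83 in heart, so this array does not check the label for HAND2. TBX5 was already at 10.19 in HFF and 10.66 in heart. MEF2C reached 12.45, above its heart value of 9.95, while MYOCD, a coactivator of serum response factor, reached 8.52 against 10.21 in heart.

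The first comparison asked what differed between transduced and untransduced fibroblasts. NPPA, which encodes atrial natriuretic peptide, was higher by 8.46, the muscle ankyrin repeat gene ANKRD1 by 8.11 and NPPB, which encodes B-type natriuretic peptide, by 7.46. Cardiac actin ACTC1 was higher by 7.09, phospholamban (PLN), a regulator of the calcium pump, by 6.85, smooth muscle myosin MYH11 by 6.59, and the atrial light chains MYL4 and MYL7 by 6.36 and 6.13. The other genes among the 15 largest were MMP12 at 7.26, GATM at 6.55, RPE65 at 6.53, PDLIM3 at 6.05, ITGB1BP2 at 5.74, PALMD at 5.67 and RGS5 at 5.61. In all, 811 genes were at least 2-fold higher and 658 at least 2-fold lower among 12891, and 309 and 154 passed 4-fold. The share higher among the changed genes was 55.2%, and 44.5% with arrays centred on the housekeeping list. A shift that set the median housekeeping difference from HFF to 0, added after seeing the data, gave 52.0%.

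At the other end, the alcohol dehydrogenase gene ADH1B differed by -6.85, dermatopontin (DPT) by -4.94, IGSF10 by -4.70, osteomodulin (OMD) by -4.57 and the steroid reductase gene SRD5A2 by -4.53. AKR1C1 and AKR1C2 differed by -4.64 and -4.40, but another cluster of AKR1C1 showed 0.00, and near-identical copies of this family make both values uncertain. The remaining genes were GRIA1 at -4.31, the procollagen processing gene PCOLCE at -4.25, fibulin 1 (FBLN1) at -4.22, PDGFRL at -4.20, KCNK2 at -4.16, TMEM119 at -4.15, the adipogenic receptor PPARG at -4.05 and ABCA6 at -4.01.

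Among 29 measured sarcomere genes, 17 were at least 2-fold higher in HFF_5F than in HFF, 0 were lower and 12 lay within 2-fold. The list median was 1.84, above all 10000 matched random lists. The median level of these genes in HFF was 5.68, below the filter of 6.85, so dim members may have had little room to fall. In HFF_5F 7 genes lay within 2-fold of their heart values, among them ANKRD1, ACTC1, MYL4 and MYL7, and titin (TTN) and SMPX were higher than HFF by 5.40 and 5.24. The other part of the list stayed near HFF. TCAP differed by 0.02, the ventricular light chains MYL3 and MYL2 by 0.09 and 0.38, LMOD2 by 0.12, cardiac troponin I (TNNI3) by 0.17, MYOM2 by 0.17 and beta myosin heavy chain (MYH7) by 0.21. Actin and myosin genes have near-identical copies, so values of ACTC1, ACTA1, MYH6 and MYH7 are uncertain where probes are shared.

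**Figure D1:**
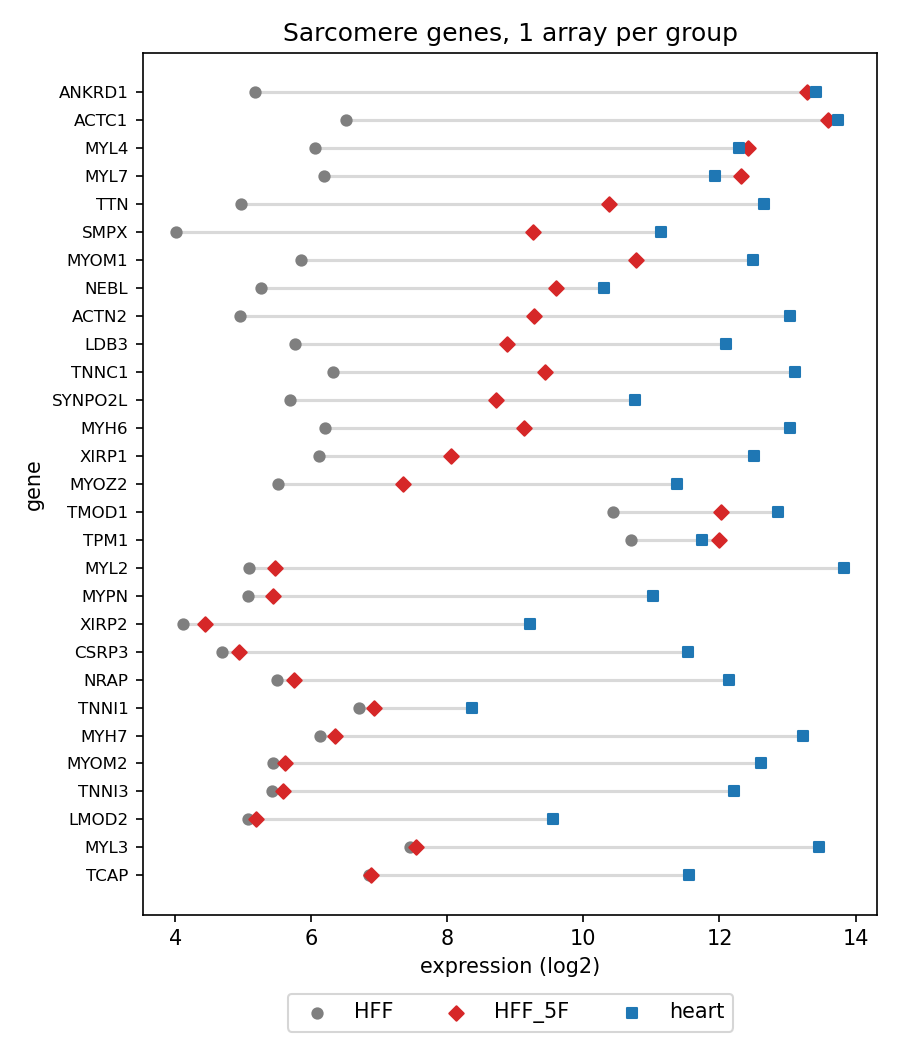
Log2 expression (x axis) of the 29 measured sarcomere genes (y axis) on the 3 arrays; each marker is 1 array and grey lines span the 3 values. HFF_5F lies within 2-fold of heart for 7 genes, among them ANKRD1, ACTC1, MYL4 and MYL7, and differs from HFF by 0.02 for TCAP, 0.09 for MYL3 and 0.21 for MYH7.

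Calcium handling genes had a median of 0.52, above all 10000 random lists, with 7 of 18 at least 2-fold higher and 0 lower. PLN was higher by 6.85, calsequestrin 2 (CASQ2) by 4.32, ITPR1 by 2.63, the junction gene JPH2 by 2.04 and the ryanodine receptor RYR2 by 1.59. Within 2-fold lay TRDN at 0.00, CACNA1C at 0.14 and SLN at 0.20. Of 20 ion channel and junction genes, 4 were higher and 0 lower, with a median of 0.30 that exceeded 9994 random lists and was 0.15 with housekeeping centring. These were the desmosomal gene PKP2 at 5.11, CDH2 at 1.85, KCNA5 at 1.23 and DSP at 1.10, while KCNJ5 differed by 0.02 and HCN4 by -0.04. Median levels in HFF were 6.83 for the calcium list and 6.62 for the ion channel list. Dim members of both may also have had little room to fall.

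Cardiac transcription factors that were not transduced differed little. Their median over 26 genes was 0.11, and -0.04 with arrays centred on the housekeeping list. TBX20 was the 1 gene at least 2-fold higher, by 1.55, and the metabolic coactivator PPARGC1A the 1 gene lower, at -2.28. NKX2-5 was equal at 8.49 in both, against 10.95 in heart. Atrial markers had a median of 0.60 over 10 genes with 4 higher, and ventricular markers 0.32 (0.17 with that centring) over 10 genes with 2 higher, NPPB and MYOZ2. The lists share members with the sarcomere list, and a difference between them was not tested.

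Smooth muscle genes were higher as a list, with 16 of 24 at least 2-fold higher and 0 lower. Their median was 1.504, above all 10000 random lists. MYH11 was higher by 6.59, desmin (DES) by 4.06, ACTG2 by 3.40 and KCNMB1 by 3.12. DES was also higher in heart than in HFF, by 5.57, so it does not set smooth muscle apart from heart here. Skeletal muscle genes had a median of 0.05, and -0.10 with housekeeping centring, with 17 of 31 below the expression filter, and ACTA1 was the 1 gene past 2-fold, higher by 5.46.

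Of 26 fibroblast identity genes, 11 were at least 2-fold lower and 1, DKK3, was higher, with a median of -0.71 below all 10000 random lists. The growth factor receptors PDGFRA and PDGFRB differed by -3.46 and -3.20, S100A4 by -2.36 and FGF7 by -2.17. Of 32 extracellular matrix genes, 11 were lower and 0 higher, with a median of -0.42 below all random lists. FBLN1 differed by -4.22, the collagen gene COL6A3 by -2.67, biglycan (BGN) by -2.08 and THBS2 by -1.93. Cell cycle genes had a median of -0.64, below all random lists, with 8 of 31 lower and 0 higher, led by KIF20A at -1.74, TOP2A at -1.37, MKI67 at -1.14 and CCNB2 at -1.14.

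Inflammatory secretion genes were higher, with 12 of 21 at least 2-fold higher, 1 lower and a median of 1.40 above all 10000 random lists. IL1B was higher by 5.23, CXCL8 by 4.85, IL1A by 4.42 and the metalloprotease gene MMP3 by 2.98. Interferon response genes had a median of -0.01, with 3 of 30 higher and 1 lower. Immediate early genes had a median of 0.00, with 1 of 17 higher and 3 lower.

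Energy metabolism genes stayed near HFF. Oxidative phosphorylation genes had a median of 0.13, and -0.02 with housekeeping centring, with 1 of 26 higher, NDUFV2 at 1.16. Fatty acid and heart energy genes had a median of 0.03, and -0.12 with housekeeping centring, with 1 of 24 higher, the fatty acid transporter CD36 at 2.61, and 1 lower, PPARGC1A. Glycolysis genes had a median of 0.10, and -0.047 with that centring, with PFKP at 1.77 the 1 of 14 past 2-fold. Housekeeping genes had a median of 0.05, with 0 of 16 past 2-fold.

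**Figure D2:**
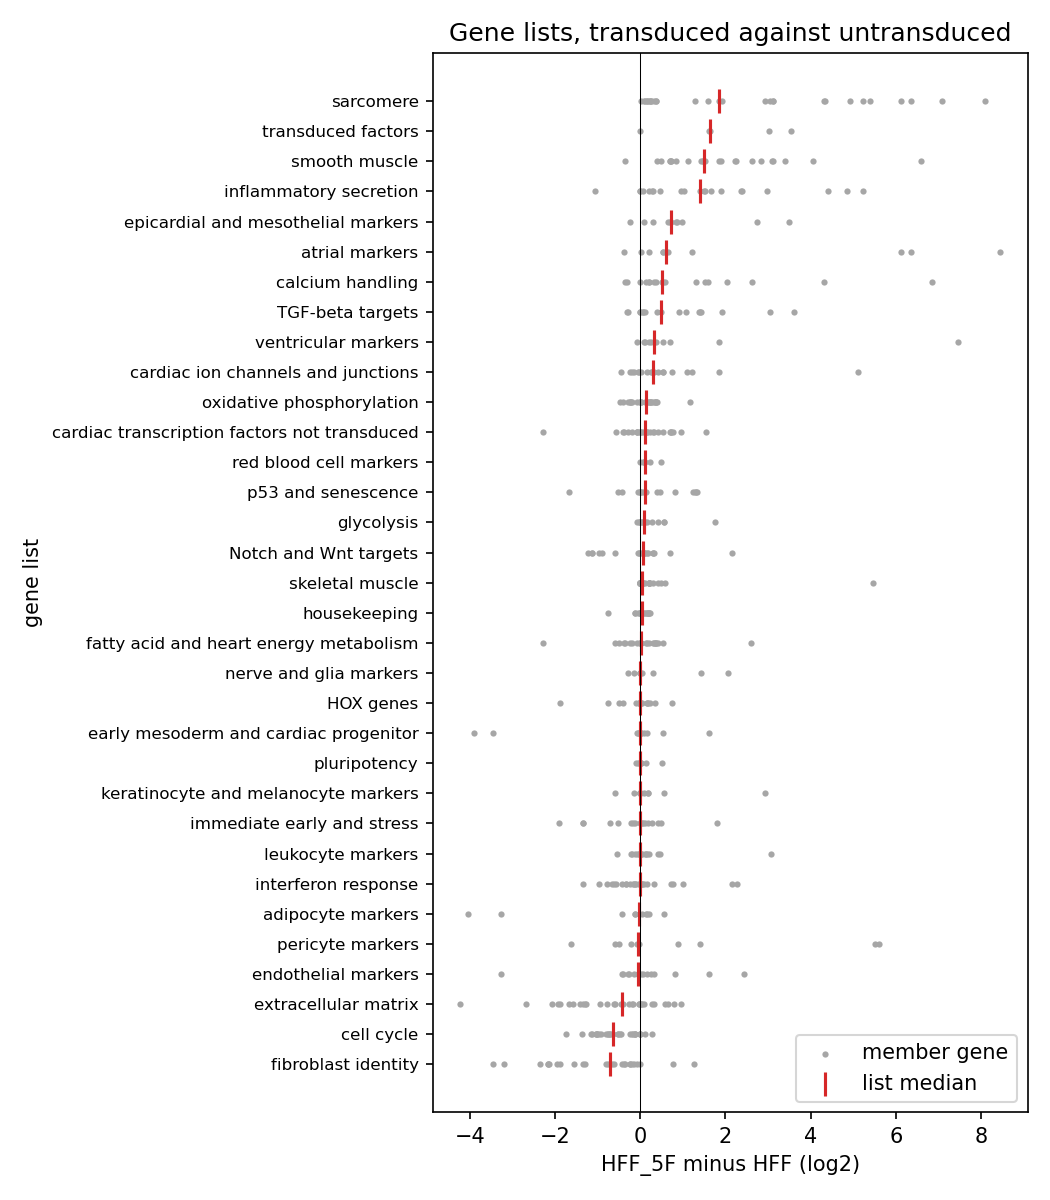
Log2 difference of HFF_5F minus HFF (x axis) for each gene list (y axis); grey points are member genes and red ticks list medians. Sarcomere, smooth muscle and inflammatory secretion have medians of 1.84, 1.504 and 1.40, and fibroblast identity -0.71.

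The second comparison set the positive against the negative control. The genes highest in heart relative to HFF were MYL2 by 8.75, TECRL by 8.74, ANKRD1 by 8.24, MLIP by 8.09, ACTN2 by 8.08, CASQ2 by 7.84, TTN by 7.68, the mitochondrial creatine kinase CKMT2 by 7.56, NPPA by 7.56 and lipoprotein lipase (LPL) by 7.48. The lowest were ACKR4 at -6.81, the fibroblast protease FAP at -6.68, DPP4 at -6.54, CEMIP at -6.50, DKK1 at -6.10, GREM1 at -5.99, MME at -5.92, SLC7A11 at -5.88, MMP1 at -5.63 and C12orf75 at -5.51. Heart was at least 2-fold higher for 1554 genes and lower for 2965, so 34.4% of the changed genes were higher. That split depended on the scaling. Centred on the housekeeping list, 2897 were higher and 2035 lower, or 58.7%, but this centring left the list itself at 0.18. With the added shift, 47.2% were higher.

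All 29 sarcomere genes were higher in heart, with a median of 6.39. Median differences were 2.58 for calcium handling, 1.54 for ion channels, 1.19 for cardiac transcription factors, 1.19 for oxidative phosphorylation and 1.95 for fatty acid genes. They were -1.86 for fibroblast identity, -1.89 for extracellular matrix and -1.99 for the cell cycle. Heart tissue also carried markers of other cells: median differences were 2.93 for endothelial, 2.91 for leukocyte, 2.60 for adipocyte, 1.31 for red blood cell, 1.20 for pericyte and 1.02 for nerve and glia markers. In HFF_5F these lists stood at -0.04, 0.00, -0.04, 0.11, -0.04 and 0.01 relative to HFF. Of the 10 pericyte markers, however, 3 were at least 2-fold higher in HFF_5F and 1 was lower. Epicardial and mesothelial markers were higher in both, with medians of 0.93 for heart and 0.72 for HFF_5F relative to HFF.

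The third comparison asked what separated HFF_5F from heart. HFF_5F was at least 2-fold higher for 2885 genes and lower for 1374, a share of 67.7% higher. That share was 32.3% with housekeeping centring, which left the housekeeping list at -0.33, and 51.4% with the added shift. The lowest genes in HFF_5F were TECRL at -8.47, MYL2 at -8.37, FABP4 at -7.45, CKMT2 at -7.25, complement C7 at -7.23, LPL at -7.09, myoglobin (MB) at -7.02, MYOM2 at -7.00, MYH7 at -6.89 and TNNI3 at -6.63. The highest were MMP12 at 7.44, EGFL6 at 6.57, DIAPH3 at 6.34, RXFP1 at 6.28, RPE65 at 6.23, HSD17B6 at 6.05, STMN2 at 5.89, MGARP at 5.86, C12orf75 at 5.83 and periostin (POSTN) at 5.75. Of 29 sarcomere genes, 22 were lower in HFF_5F and 0 higher, with a median of -3.77. Medians were -1.65 for calcium handling, -1.76 for fatty acid genes and -1.20 for oxidative phosphorylation. Extracellular matrix and cell cycle genes were higher in HFF_5F than in heart by medians of 1.09 and 1.12, or 0.52 and 0.54 with housekeeping centring. Smooth muscle and inflammatory secretion genes were also higher, by medians of 1.22 and 1.10, with 13 of 24 and 12 of 21 at least 2-fold higher. Housekeeping centring lowers these medians too, since it moved the median of all genes by -0.58.

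The position of HFF_5F between the controls was read from the control-enriched genes. It does not describe genes that passed both controls. Of the 811 genes at least 2-fold higher in HFF_5F than in HFF, 472 were also at least 2-fold above heart. Both differences use the HFF_5F array, and this count was not recomputed with other scalings. Of 622 heart-enriched genes, 202 were at least 2-fold higher in HFF_5F than in HFF (32.5%, exact 95% interval 28.8 to 36.3) and 7 were lower. Heart-enriched genes that were dim in HFF may have had little room to fall. Of 1126 fibroblast-enriched genes, 253 were lower in HFF_5F (22.5%, exact 95% interval 20.1 to 25.02) and 44 were higher. Among 8372 genes within 2-fold between heart and HFF, 4.20% were higher and 2.21% lower. The median heart-enriched gene had covered 13.2% of the log2 gap to heart and the median fibroblast-enriched gene 12.2%. With housekeeping centring the shares moved were 25.4% and 30.4% and the gaps covered 6.64% and 19.96%, so which side moved further depends on the scaling. The gap was covered by at least 80% for 74 heart-enriched genes, by 20 to 80% for 184 and by under 20% for 364.

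Both differences share the HFF array. In simulations of unchanged cells, 0.139% of heart-enriched genes moved with array noise from the robust spread of HFF_5F minus HFF, and 9.17% with the wider spread of a block of unnamed clusters, whose content is not known here. The covariance of the differences was 0.465, against simulated values of 0.0509 and 0.190. Genes higher in both HFF_5F and heart numbered 341 and genes lower in both 449, where independent lists would share 97.8 and 151. Simulated unchanged cells, which share the HFF array, gave means of 3.07 and 4.04 with the robust spread, and 219 and 286 with the wider spread, at most 266 and 345. These simulations show only what noise of each size and the shared array give. Cells that changed as much but without relation to heart were not simulated, so a shared direction with heart was not tested. Across genes, which are not independent replicates, Pearson's r was 0.867 between HFF_5F and HFF, 0.642 between HFF_5F and heart and 0.598 between heart and HFF. Spearman's rho was 0.876, 0.641 and 0.607.

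**Figure D3:**
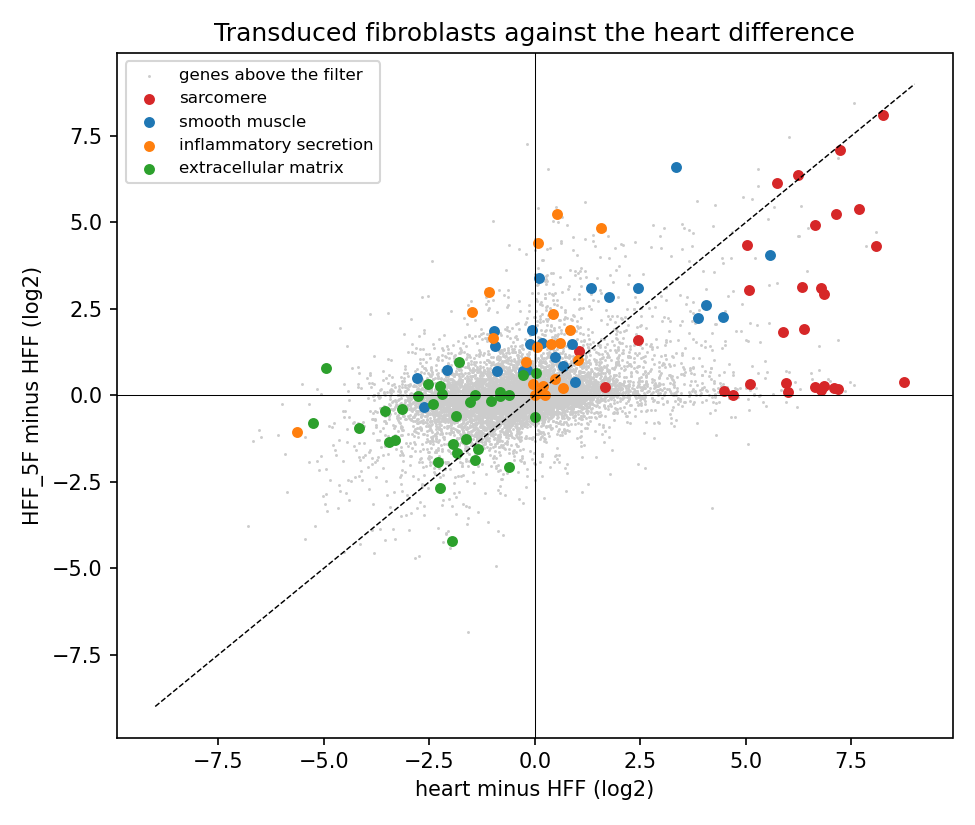
Log2 difference of HFF_5F minus HFF (y axis) against heart minus HFF (x axis) for the 12891 genes above the filter (grey), with members of 4 gene lists coloured; the dashed line marks equality with heart. Sarcomere genes range from ANKRD1 at 8.11 to TCAP at 0.02, and 22 of the 29 lie at least 2-fold below heart.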

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

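All tests in this part were chosen after the result was seen. Clusters that the comparisons did not use also differed between HFF_5F and HFF. Of 4203 clusters without a listed gene whose identifiers come before the first annotated one, 16.2% passed 2-fold, with 42 higher and 637 lower, and their mean difference was -0.41. What these clusters measure is not known here, and control probe sets are not ruled out, so these differences cannot be read as expression of genes. Of 7880 other clusters without a listed gene, 99 were higher and 118 lower. Of 1754 clusters of several genes, 49 were higher and 40 lower.

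The heart-enriched genes ranged from HFF level to heart level in HFF_5F, with 184 of 622 at 20 to 80% of the log2 gap. Heart RNA as the 1 source would give each gene the same linear share of the heart signal. So would a part of the cells with the whole heart muscle profile. Among 27 heart-enriched sarcomere genes, 14.8% were at a share of 80% or more and 48.1% at under 5%. These shares argue against either as the 1 source for the sarcomere. The 202 heart-enriched genes that moved had a median share of 34.1%, but 5 of the 10 genes highest in heart relative to HFF, MYL2 and TECRL among them, lay 4-fold or more below the level it needs, which argues against heart RNA as their 1 source. In an earlier test over all 622 heart-enriched genes, 9.0% were at 80% or more, short of its bound of 10%. Another test was dropped because its best share was close to no heart RNA. Heart RNA at 5% of the heart signal or more would lift each of the 27 sarcomere genes to that share. The 48.1% of them at under 5% argue against it for the sarcomere. The first quartile of the 27 shares was 0.18%, which also argues against a part well above 0.18% for these genes. Heart RNA as a part smaller than that cannot be told apart. Whether culture time, vector or selection and not the factors made this range cannot be told apart, with 0 arrays of vector-only or time-matched cells.

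Inflammatory genes such as IL1B and CXCL8 were higher in HFF_5F. Leukocytes in the culture would bring their markers, yet the bootstrap interval of the leukocyte list median ended at 0.14, with CD14 at 3.07 the 1 marker past 2-fold while LYZ, abundant in myeloid cells, differed by 0.21. Of 30 interferon response genes, 7 were below the expression filter, CXCL11 among them. For an interferon response to the vector, the interval of the interferon list ended at 0.021 and its median was 0.029 when quantile normalized again. In that list CXCL11 at 2.27, IFI27 at 2.16, IFI6 at 1.01 and IFIT1 at -1.34 passed 2-fold. These values argue against a 2-fold rise of either list as a whole, not against a rise of single members. Culture time, vector or selection and not the factors cannot be told apart from the factors, again with 0 such arrays, and the factors themselves stay an untested explanation.

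Equal values, counted where the log2 difference was under 1e-06, were frequent: 30.8% of all clusters were equal in HFF_5F and HFF, 60.9% in the dimmest of 10 expression bins and 4.26% in the brightest. Rounding of the deposited values would also give many near-equal values, but 0.0721% differed by under 0.001 without being equal. Median polish of RMA over 3 arrays may be the source, since it made at least 76.3% of simulated unchanged clusters equal and the mean over probes made 0%. HAND2 may be equal because its probes lie outside the transduced sequence, but this cannot be told apart from an unchanged level: the other 4 factors were higher by at least 1.62, and probe-level values were not used here.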

How the results depend on the processing

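The shift by housekeeping differences and the run without other cell type markers were chosen after seeing the data. The planned housekeeping centring, on the level of the list, left the list itself at 0.18 for heart minus HFF, so a shift by its median difference was added beside it. No paired analysis was possible because each group had 1 array and no test was run. The sarcomere, calcium, ion channel, smooth muscle, fibroblast and inflammatory medians of HFF_5F minus HFF stayed inside their bootstrap intervals over members under every alternative tried. The scaling set the balance of higher and lower genes. Housekeeping centring moved the median of all genes by -0.15 for HFF_5F minus HFF, 0.43 for heart minus HFF and -0.58 for HFF_5F minus heart, and the added shift moved them by -0.05, 0.25 and -0.30, so small differences have no settled sign. No replicate spread or signal over background was at hand to say how small a difference these arrays resolve. Of 3168 recomputed gene differences, 2816 moved by less than the robust spread of HFF_5F minus HFF and 352 by more, 347 of them under housekeeping centring, and 0 past 2-fold reversed. The array-median, housekeeping and added-shift scalings subtract 1 constant per array. Within a comparison they moved every gene by the same amount, always under 1, so they could not reverse a 2-fold difference. Of 690 list medians 628 stayed in their interval. Of 99 list percentiles 82 moved by 5 points or less with random lists matched on HFF alone.

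With a 4-fold threshold, genes higher and lower were 309 and 154 for HFF_5F against HFF, 622 and 1126 for heart against HFF, and 1093 and 494 for HFF_5F against heart. With 1.5-fold, 1499 were higher and 1422 lower in HFF_5F than HFF, 2687 higher and 4164 lower in heart than HFF, and 4044 higher and 2516 lower in HFF_5F than heart. These follow from the threshold. Housekeeping centring gave 2897 genes higher in heart than HFF, and 1705 higher and 3570 lower in HFF_5F than heart. The higher share was then 44.5%, 58.7% and 32.3% in the 3 comparisons. The added shift gave 2109 genes lower in HFF_5F than heart, and higher shares of 52.0%, 47.2% and 51.4%. The share of heart-enriched genes higher in HFF_5F was 25.4% with housekeeping centring, 38.1% with 8-fold enrichment, 21.9% with 2-fold enrichment and 44.4% when 1.5-fold counted as moved. The share of fibroblast-enriched genes lower in HFF_5F was 30.4%, 35.9%, 15.1% and 36.8% in the same order, and 26.4% with the added shift. The median gap covered was 6.64% for heart-enriched and 19.96% for fibroblast-enriched genes with housekeeping centring, and 10.6% and 15.8% with the added shift. For fibroblast-enriched genes it was 9.95% with cyclic loess and 17.0% with 8-fold enrichment. Without other cell type markers, 33.3% of heart-enriched genes were higher. Over all genes Pearson's r was 0.945 for HFF_5F and HFF, 0.828 for heart and HFF and 0.849 for HFF_5F and heart.

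Centred on the housekeeping list, list medians were skeletal muscle -0.10, p53 and senescence -0.045, fatty acid -0.12, glycolysis -0.047, leukocyte -0.15, red blood cell -0.045, nerve and glia -0.14, keratinocyte -0.15, HOX -0.15, pluripotency -0.15, early mesoderm -0.15, housekeeping -0.10 for HFF_5F minus HFF. They were skeletal muscle 0.90, extracellular matrix -1.47, p53 and senescence -0.34, interferon 0.46, inflammatory secretion 0.63, keratinocyte 0.78, HOX 0.65, pluripotency 0.71, early mesoderm 0.84, housekeeping 0.18 for heart minus HFF. They were skeletal muscle -0.92, extracellular matrix 0.52, cell cycle 0.54, oxidative phosphorylation -1.78, glycolysis -0.63, interferon -0.67, keratinocyte -0.88, pericyte -1.75, HOX -0.77, pluripotency -0.74, early mesoderm -1.04, housekeeping -0.33 for HFF_5F minus heart. Shifted by the housekeeping differences, list medians were skeletal muscle 0.72, p53 and senescence -0.52, interferon 0.28, keratinocyte 0.59, HOX 0.47, pluripotency 0.53, early mesoderm 0.66 for heart minus HFF. They were skeletal muscle -0.64, interferon -0.39, keratinocyte -0.60, HOX -0.49, pluripotency -0.46, housekeeping -0.048 for HFF_5F minus heart. They were leukocyte -0.051, keratinocyte -0.051, HOX -0.051, pluripotency -0.051 for HFF_5F minus HFF. With cyclic loess, list medians were skeletal muscle 0.34, early mesoderm 0.30 for heart minus HFF. They were skeletal muscle -0.19 for HFF_5F minus heart. They were keratinocyte -0.0014, HOX 0.012 for HFF_5F minus HFF. Quantile normalized again, list medians were p53 and senescence -0.57 for heart minus HFF. They were interferon 0.029, HOX 0.036 for HFF_5F minus HFF. Without dim members, list medians were skeletal muscle 1.67 for heart minus HFF. They were skeletal muscle -1.06 for HFF_5F minus heart. Centred on array medians, list medians were HOX 0.029 for HFF_5F minus HFF. Of 33 list medians of HFF_5F minus HFF, 10 turned sign with housekeeping centring and 2 with the added shift, all within 0.15 of 0 at first. For HFF_5F minus heart, fibroblast identity turned from 0.43 to -0.14 with housekeeping centring. Apart from the scalings and thresholds themselves, the cause was not tested.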

Other observations

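Signalling and positional genes held several differences between HFF_5F and HFF. TGF-beta targets had a median of 0.49, above all 10000 random lists, with 7 of 17 at least 2-fold higher and 0 lower: TGFB2 by 3.62, INHBA by 3.06 and CCN2 by 1.93. The p53 and senescence list had a median of 0.10, and -0.045 with housekeeping centring, with 4 of 16 higher, among them GDF15 at 1.33 and TP53I3 at 1.32, and 1 lower, HMGB2 at -1.66. HMGB2 and LMNB1 were listed as genes that fall in senescence, so the list median mixes members expected to move in opposite directions. Notch and Wnt genes, 2 of 20 below the filter, had a median of 0.06, and -0.088 with housekeeping centring. LEF1 was higher by 2.16 and JAG1, DKK1 and WIF1 were lower at -1.12, -1.14 and -1.22. HOX genes, which mark body position, had a median of 0.00, with HOXC10 at -1.88 the 1 of 27 past 2-fold and 14 below the filter. Pluripotency genes had a median of 0.00 with 0 of 10 past 2-fold, but 9 of these were below the expression filter and 2 more were not analysed here, so the count says little. Early mesoderm genes had a median of 0.00, with KDR at 1.61, PDGFRA at -3.46 and FGF10 at -3.91 past it.

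Epicardial and mesothelial markers had a median of 0.72 (bootstrap interval 0.29 to 0.97), above 9997 of 10000 random lists, with CALB2 at 3.49 and KRT18 at 2.75. Among pericyte markers RGS5 and MCAM were higher by 5.61 and 5.51 and ABCC9 differed by -1.62. Nerve and glia markers, 5 of 9 below the filter, included NCAM1 at 2.06, and keratinocyte and melanocyte markers, with a median of 0.00 and 8 of 13 below the filter, included DSC3 at 2.93. Endothelial markers included AQP1 at 2.44 and FABP4, also an adipocyte marker, at -3.26. In HFF_5F, 472 of the 811 genes higher than HFF were at least 2-fold above both controls. Another 145 genes were at least 2-fold below both. Furthest above were MMP12, RPE65, GKN2, HSD17B6, CLDN1, IL1B, TAGLN3 and CDH8, where GKN2 was higher than HFF by 5.41 and the tight junction gene CLDN1 by 5.44. Furthest below were ADH1B, DPT, PPARG, FABP4, ADH1C, the iron exporter SLC40A1, SELENOP and GALNT16, where ADH1C differed from HFF by -3.93 and SLC40A1 by -2.96.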
